A study of Homo sapiens with 15 samples.

How the data were processed

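Gene expression was measured in human monocyte-derived dendritic cells on Affymetrix HG-U133 Plus 2.0 arrays, which read each transcript with 1 or more probe sets. Per the labels, the cells were kept in a serum-containing medium and either left uninfected or given metacyclic promastigotes of Leishmania major, the infective form of the parasite, coated with human serum. RNA was extracted on columns and biotin-labelled for the arrays, per the labels. The 15 arrays form 5 groups of 3: uninfected at 2 h, and infected at 2, 4, 8 and 24 h. Replicates 1, 2 and 3 of each group were taken as 3 donors. No genome sequence was used, so genes are given by symbol without coordinates.

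The deposited value table holds an intensity for each of 54613 probe sets on each array, on a linear scale from 1.42 to 66682. Per the submitters' processing notes the values were made with GCRMA, and its version and any later step are not given in the sources used here. A table of 848 probe sets that the authors deposited beside it holds an intensity per array, a p-value per probe set and a fold change per time point. The p-value in the authors' deposited table runs from 2.63e-09 to 0.000297, and its test is not given in the sources used here. A one-way analysis of variance on the linear values of that table gave the deposited p-value with a median ratio of 1. The fold changes the authors deposited are a ratio of group means on the linear scale, and they were recomputed from that table's own array columns to within a relative difference of 1.5e-08. The intensities of the authors' deposited table are not those of the value table: 60.3% of them recur in 2 or more arrays, against 0.794% in the value table, and matched arrays are offset by -0.18 to 0.20 on the log2 scale.

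The sample labels and the array names of the authors' deposited table conflict. Each of its 15 array columns was matched to the value table by the correlation of log2 intensities across the 848 probe sets, and each had 1 clear match, with a lowest r of 0.999 for matches and a highest r of 0.990 for any other array. In 0 of 15 matches did the condition agree: the conditions are displaced by 1 place, while the replicate order is the same. Groups were taken from the sample labels. The same fits were also read by the array names of the authors' deposited table, a reading added after the data were seen, which rests on that match of columns. Groups under the labels are called labelled, and groups under those array names are called listed.

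Values were used as log2 of the intensity plus 1. A probe set was kept if it exceeded 4 on the log2 scale on at least 3 of the 15 arrays, which left 19566. Of all probe sets, 41091 name 1 gene, 1801 name several and 11721 name none; symbols of 41037 were updated through their gene identifiers. Of the kept probe sets 17019 name 1 gene, and for each gene the probe set with the highest mean was used, which gave 9689 tested genes. Probe sets with several genes or none were left out of gene counts. The median log2 level of the tested genes lies between 7.15 and 7.76 on the 15 arrays. Arrays have no read depth; their number limits the precision, with 3 arrays per group. No Affymetrix control probe sets are in the value table, so RNA quality was not analysed here.

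The fits used limma 3.58.1 in R 4.3.3: 1 mean per group over all 15 arrays, then moderated tests with an intensity trend, two-sided. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison, with no minimum fold. Where a named gene had a mean under 4 in 1 group, its change was also computed with that group taken at 4, as a lower bound in size, a step added after the data were seen. Errors are SE from that fit unless stated otherwise, with n = 3 arrays in each group. The comparisons are each infected time against uninfected 2 h, infected 4 h against 2 h, 8 h against 4 h, 24 h against 8 h and 24 h against 2 h, and limma's F test over the 5 groups. Infected 24 h against infected 4 h was added after the data were seen, because the array names of the authors' deposited table make it uninfected 2 h against infected 8 h. These choices, the lists and the rule for naming genes were otherwise made before the data were examined.

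The arrays were taken as paired by donor, with the replicate number standing for the donor. After group means were removed, arrays with the same replicate number correlated across genes in all 30 pairs (r from 0.15 to 0.74, median 0.49), and pairs with different numbers had r from -0.56 to 0.14 in 60 pairs (median -0.25). The fit without donor stays the main one, as planned. The fit with the replicate number as a block is given where it moves a count of called genes by more than 1.5 times, and for some calls of genes and lists. The block called more genes in every comparison. Counts of list members not called rest on the fit without donor unless stated, and may be lower with the block.

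For 34 fixed lists of 656 genes, 24 of pathways and 10 of cell type markers, each comparison has the number of genes measured, higher, lower and not called, and the number called when adjusted over the list alone. The pathway lists cover interferon-stimulated genes, interferon signalling and IRF/STAT factors, nucleic acid and pattern recognition receptors, NF-kB pathway genes, inflammatory cytokines, chemokines, T-cell polarising cytokines, dendritic cell maturation and co-stimulation, MHC class I presentation, MHC class II presentation, C-type lectin, Fc, complement and scavenger receptors, and phagosome, oxidase and lysosome genes. They also cover glycolysis and hypoxia response, mitochondrial oxidative phosphorylation, cholesterol synthesis and uptake, liver X receptor targets and lipid efflux, metallothioneins, NRF2 and oxidative stress genes, heat shock and unfolded protein response, immediate early genes, tryptophan, arginine and prostaglandin enzymes, cell death regulators, cell cycle, and ribosomal proteins. The cell type lists hold markers of T cells, B cells, NK cells, monocytes, macrophages, monocyte-derived dendritic cells, plasmacytoid dendritic cells, platelets, erythroid cells and neutrophils. Each list with at least 2 measured genes, 32 of the 34, was tested against all other genes with camera at a preset correlation between genes of 0.01, with p adjusted over the lists. The test was repeated with an estimated correlation and with fry.

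Named genes follow a rule: in each comparison with uninfected arrays, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, and up to 4 members of each list with the largest change. Between infected times the 5 largest on each side are used, and a gene named once may be followed elsewhere. Genes that mark a person's sex, segments of immune receptors and genes with common deletions were left out.

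The steps were tested on simulated data with the 9689 genes and the arrays of infected 4 h against uninfected 2 h. With changes put into 50 genes at each size, 4 were called at a 1.5-fold change, 27 at 2-fold, 45 at 4-fold and 50 at 8-fold. With those 200 genes changed, 134 genes were called in all, 8 of them unchanged. With no change put in, 0 genes were called by limma. Of the 32 lists, 1 was called when 1 list was raised and 0 when none was. The simulated noise was drawn independently for each gene and array. Correlation between genes and the pairing by donor were therefore not part of it, and the list test was not tried on correlated genes.

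The alternatives tried were a replicate block, no dim filter and a stricter one (above 6), quantile normalization, arrays shifted to a common median, the mean of all probe sets of a gene, only the arrays of the 2 groups compared, limma without the trend, adjusted p under 0.01, a minimum of 2-fold, a pseudocount of 16, probe sets in place of genes, camera with an estimated correlation, fry, and leaving out each array in turn. Figures were drawn with Python 3.11 and matplotlib 3.10.9.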

Results

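Transcript levels were measured in human monocyte-derived dendritic cells, antigen-presenting cells grown in culture from blood monocytes, with and without Leishmania major, a protozoan parasite that lives inside phagocytes. The labels give 15 arrays in 5 groups of 3: uninfected cells at 2 h and infected cells at 2, 4, 8 and 24 h. Each group has replicates 1, 2 and 3, and the replicate number was taken as the donor. The deposited intensities have a median per array between 7.04 and 7.99 on the linear scale, and 9689 genes were bright enough to be tested. There is no uninfected array after 2 h, so by either set of names infection and time in culture change together at 4, 8 and 24 h.

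The sample labels and the authors' deposited table name the same arrays differently. The arrays labelled uninfected 2 h are listed in the authors' deposited table as infected 2 h. The arrays labelled infected 2 h are listed as infected 4 h, those labelled infected 4 h as infected 8 h, and those labelled infected 8 h as infected 24 h. The arrays labelled infected 24 h are listed as uninfected 2 h. The match of columns behind this has a lowest correlation of 0.999 across 848 probe sets, against at most 0.990 for any other array; probe sets are not independent replicates. The files do not settle which names are right, so each comparison gives both, labelled first and listed second, and the listed names were taken up after the data were seen.

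**Figure D1:**
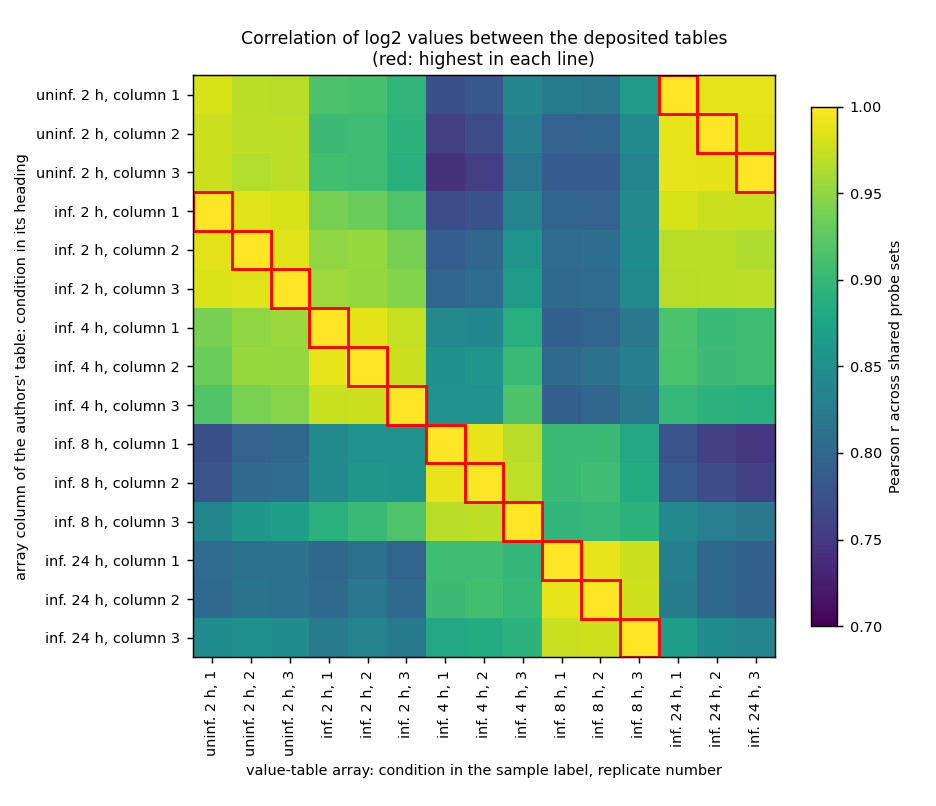
Correlation (Pearson's r, colour) of log2 intensities across the 848 probe sets of the authors' deposited table, with its 15 array columns on one axis under their listed names and the 15 arrays of the value table on the other under their labels. Each column has 1 match, with r of 0.999 or more, and each match lies 1 condition away from its label.

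Across the 5 groups, 4568 of 9689 genes differed by limma's F test, a count that does not depend on the names of the groups. The arrays labelled uninfected 2 h (listed infected 2 h) and those labelled infected 24 h (listed uninfected 2 h) were the closest pair of groups, with a correlation of group means across genes of 0.991; the other pairs had 0.928 to 0.982.

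**Figure D2:**
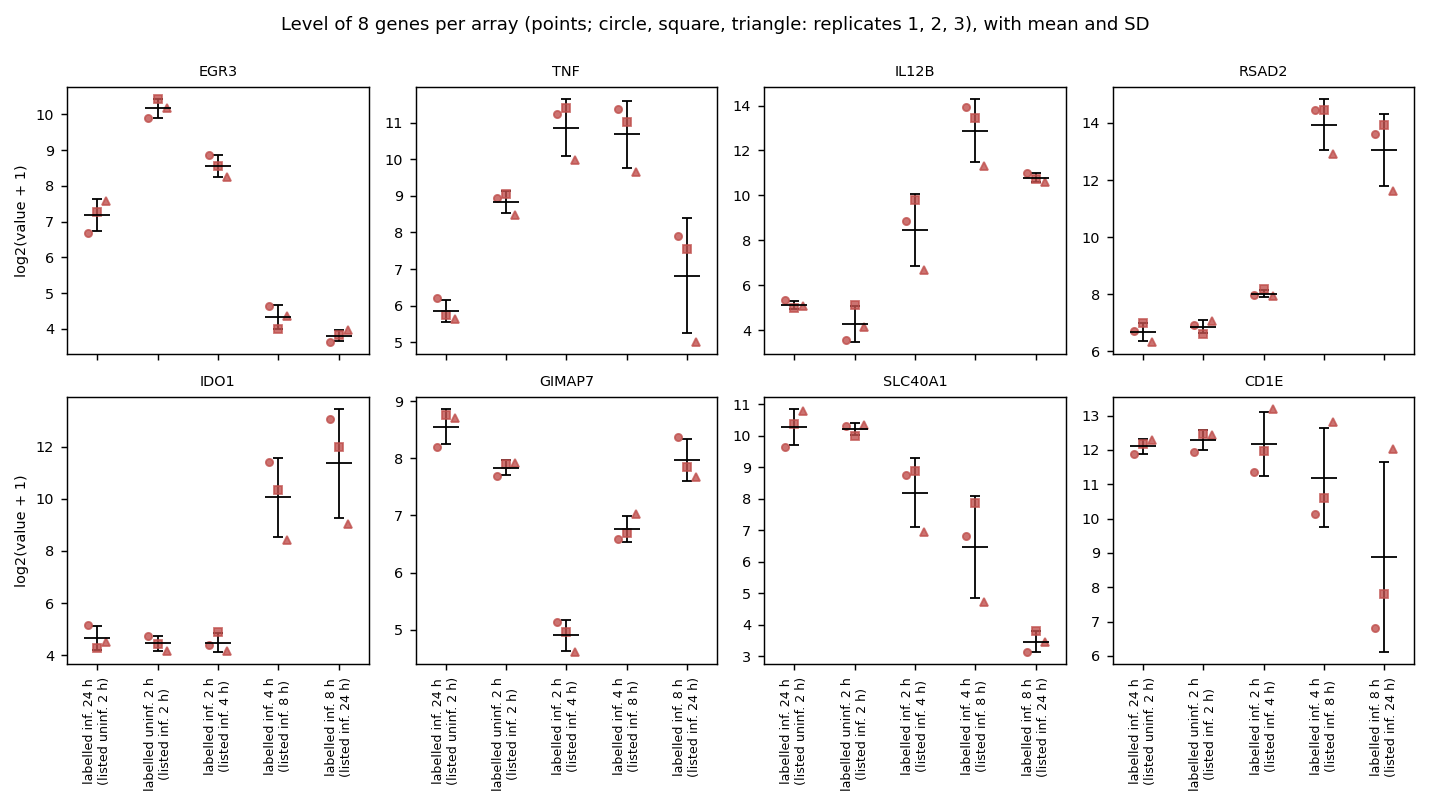
Level (log2 intensity) of 8 genes on each of the 15 arrays, by group under both names, with the mean of 3 arrays as a bar. IL12B, RSAD2 and IDO1 are highest in the arrays labelled infected 4 h and 8 h (listed 8 h and 24 h), EGR3 is highest in the arrays labelled uninfected 2 h (listed infected 2 h), and TNF has its lowest group mean in the arrays labelled infected 24 h (listed uninfected 2 h).

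Infected 2 h against uninfected 2 h, the question of the earliest response, is by the labels the only comparison matched for time. Listed, it is infected 4 h against infected 2 h. CSF1, a macrophage growth factor, was higher by 2.09 ± 0.31 on the log2 scale (adjusted p = 0.0047). The glucose transporter SLC2A3 was higher by 1.74 ± 0.20 and the sterol sensor INSIG1 by 1.65 ± 0.14. GIMAP1, GIMAP7 and GIMAP2, GTPases of the immune system, changed by -3.19 ± 0.24, -2.94 ± 0.22 and -2.51 ± 0.23 (adjusted p = 5.16e-05 for GIMAP1). GIMAP1 lies under the filter bound of 4 in 1 group; with that group taken at 4 its change, a lower bound in size, is -2.38. IL12B, a subunit of interleukin 12, had log2 levels of 8.875, 9.805 and 6.681 in labelled infected 2 h replicates 1, 2 and 3. It was higher there by 4.18 ± 0.75 (adjusted p = 0.0134). This call was lost without uninfected replicate 1 (adjusted p = 0.0846), infected 2 h replicate 1 (0.0615) or infected 2 h replicate 2 (0.0600). Of 20 NF-kB pathway genes measured, 3 were higher, 0 lower and 17 not called (5 called when adjusted over the list alone), among them ICAM1 at 1.58 ± 0.23; the list median was 0.60, and 0.86 after arrays were shifted to a common median. Its list test gave adjusted p = 3.73e-13, and adjusted p = 0.0919 with an estimated correlation (0.0483 with the replicate block as well). Of 20 dendritic cell maturation and co-stimulation genes, 2 were higher, 0 lower and 18 not called (4 when adjusted over the list alone). The median was 0.60 (common median 0.87), and the list test gave adjusted p = 4.52e-10, or adjusted p = 0.0375 with an estimated correlation. Of 16 inflammatory cytokines 1 was higher, 0 lower and 15 not called (6 when adjusted over the list alone). The median was 1.21 (common median 1.47), and the list test gave adjusted p = 3.34e-06, but adjusted p = 0.208 with an estimated correlation (0.0483 with the replicate block as well). Among 42 interferon-stimulated genes limma called 0 (0 when adjusted over the list alone), against 2 at an unadjusted p under 0.05 and 0 with the replicate block. Their median was -0.11 and their mean -0.10, while the list test against other genes pointed up without passing (adjusted p = 0.234), and the median was 0.16 on a common median. That test passed without uninfected replicate 1 (adjusted p = 0.0268; median 0.02).

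In total 261 genes were called in this comparison, 54 higher and 207 lower, and 765 with the replicate block and 43 with only the arrays of the 2 groups. Groups did not overlap in 25.4% of genes, where chance gives 10%. The median change of all genes was -0.185, and the share of called genes that were lower was 79.3%, 61.0% after quantile normalization and 43.3% on a common median. The count was 62 without uninfected replicate 1, 131 without uninfected replicate 3, 95 without infected 2 h replicate 1, 78 without infected 2 h replicate 2 and 418 without infected 2 h replicate 3. ICAM1 lost its call when only the arrays of the 2 groups were fitted (adjusted p = 0.0815).

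Infected 4 h against uninfected 2 h asks what the response holds by 4 h. Listed, it is infected 8 h against infected 2 h. IL12B was higher by 8.62 ± 0.75 on the log2 scale (adjusted p = 4.36e-05; 9.41 without infected 4 h replicate 3), the chemokine CXCL10 by 8.31 ± 1.14 (9.34 without the same array, 7.71 without infected 4 h replicate 1) and the antiviral gene RSAD2 by 7.07 ± 0.53 (134-fold; adjusted p = 1.89e-05). The transcription factors EGR3, NR4A2, EGR1 and FOS changed by -5.84 ± 0.25 (adjusted p = 1.14e-07), -4.38 ± 0.39, -4.32 ± 0.55 and -4.02 ± 0.70. THBD, a thrombin receptor, changed by -4.95 ± 0.72 and the receptor GPR34 by -4.89 ± 0.64. Some genes lie under the filter bound of 4 in 1 group. With that group taken at 4, the lower bounds in size are 7.46 for CXCL10, -3.82 for FOS, -4.64 for GPR34, and among the lists below 4.89 for ISG20 and 3.51 for TNFRSF9. Of 42 interferon-stimulated genes measured, 33 were higher, 0 lower and 9 not called (34 when adjusted over the list alone), with ISG20 at 5.48 ± 0.67, OASL at 5.17 ± 0.73 and IFIT2 at 4.78 ± 0.62. Their median was 2.39 (common median 2.72) and the list test gave adjusted p = 4.23e-32, but adjusted p = 0.122 with an estimated correlation (0.0430 with the replicate block as well). Of 20 maturation and co-stimulation genes 12 were higher, 0 lower and 8 not called (14 when adjusted over the list alone), with TNFRSF9 at 4.30 ± 0.65 and CD40 at 2.95 ± 0.45. The median was 1.44 (common median 1.78), and the list test gave adjusted p = 1.4e-11, or adjusted p = 0.0235 with an estimated correlation. Of 19 interferon signalling and IRF/STAT factors 5 were higher, 3 lower and 11 not called (10 when adjusted over the list alone), with IRF1 at 2.80 ± 0.42 and IRF7 at 2.42 ± 0.25. The median was 0.57 (common median 0.91), and the list test gave adjusted p = 0.00353, but adjusted p = 0.175 with an estimated correlation. Of 23 nucleic acid and pattern recognition receptors 5 were higher, 4 lower and 14 not called (9 when adjusted over the list alone): RIGI rose by 3.78 ± 0.69 and IFIH1 by 2.58 ± 0.24. The median of those receptors was -0.27, their mean 0.19 and their list test pointed up (adjusted p = 0.0632); on a common median 7 were higher and 0 lower, and the test passed without uninfected replicate 1 (adjusted p = 0.0185) or infected 4 h replicate 3 (0.00477). Of 20 NF-kB pathway genes 8 were higher, 1 lower and 11 not called (11 when adjusted over the list alone), with TRAF1 at 2.61 ± 0.37 and NFKB1 at 1.97 ± 0.32. The median was 0.82 (common median 1.16), and the list test gave adjusted p = 9.13e-08, but adjusted p = 0.163 with an estimated correlation. Of 16 inflammatory cytokines 5 were higher, 1 lower and 10 not called (9 when adjusted over the list alone), with IL15 at 2.48 ± 0.49. The median was 1.57 (common median 1.91), and the list test gave adjusted p = 4.72e-05, but adjusted p = 0.191 with an estimated correlation. Of 21 immediate early genes 3 were higher, 9 lower and 9 not called (12 when adjusted over the list alone), with a median of -0.68 (common median -0.34); the list test did not pass (adjusted p = 0.369).

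In total 2732 genes were called at labelled 4 h, 635 higher and 2097 lower, and 1246 with only the arrays of the 2 groups. Their groups did not overlap in 41.2% of genes, where chance gives 10%. The median change of all genes was -0.258, and the share of called genes that were lower was 76.8%, 60.6% after quantile normalization and 40.1% on a common median. The count was 1600 without uninfected replicate 1, 1615 without infected 4 h replicate 1 and 1614 without infected 4 h replicate 2.

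Infected 8 h against uninfected 2 h asks what the response holds by 8 h. Listed, it is infected 24 h against infected 2 h. IDO1, an enzyme that degrades tryptophan, was higher by 6.89 ± 0.87 on the log2 scale (adjusted p = 0.000326; 8.05 without infected 8 h replicate 3, 6.05 without replicate 1) and EBI3, a cytokine subunit, by 5.50 ± 0.48 (adjusted p = 3.38e-05). CCR7, the receptor that guides dendritic cells to lymph nodes, was higher by 4.34 ± 0.50 and LAMP3, a marker of mature dendritic cells, by 3.32 ± 0.45. THBD changed by -7.11 ± 0.72, the iron exporter SLC40A1 by -6.75 ± 0.68 (adjusted p = 8.58e-05 for both), EGR3 by -6.36 ± 0.25 and the receptor CD93 by -5.13 ± 0.84. For genes under 4 in 1 group, the changes with that group taken at 4 are lower bounds in size: 4.92 for EBI3, -6.30 for THBD, -6.21 for SLC40A1, -6.17 for EGR3, and below 4.44 for CXCL10, 3.81 for CXCL9 and -3.48 for TNFSF18. RSAD2 was higher by 6.19 ± 0.53, with log2 levels of 13.618, 13.932 and 11.625 in labelled infected 8 h replicates 1, 2 and 3. Of 42 interferon-stimulated genes, RSAD2 among them, 32 were higher, 0 lower and 10 not called (37 when adjusted over the list alone), with IFI44L at 4.13 ± 0.65. Their median was 2.14 (common median 2.43) and the list test gave adjusted p = 5.7e-33, but adjusted p = 0.107 with an estimated correlation (0.0439 with the replicate block as well). Of 18 MHC class I presentation genes 9 were higher, 0 lower and 9 not called (11 when adjusted over the list alone), with NLRC5 at 2.50 ± 0.46 and TAP1 at 2.02 ± 0.32. The median was 0.47 (common median 0.77), and the list test gave adjusted p = 1.55e-09, but adjusted p = 0.107 with an estimated correlation (0.0439 with the replicate block as well). Of 20 MHC class II presentation genes 0 were higher, 4 lower and 16 not called (6 when adjusted over the list alone), with CD1C at -1.68 ± 0.38. Their median was -0.14 as deposited and 0.16 on a common median, and the list test did not pass (adjusted p = 0.960). Of 24 C-type lectin, Fc, complement and scavenger receptors 1 was higher, 10 lower and 13 not called (13 when adjusted over the list alone), with CLEC4A at -3.39 ± 0.63 and CLEC5A at -3.28 ± 0.68. The median was -1.10 (common median -0.80), and the list test gave adjusted p = 0.0196, but adjusted p = 0.211 with an estimated correlation. Of 20 chemokines 4 were higher, 2 lower and 14 not called (6 when adjusted over the list alone): CXCL10 rose by 5.29 ± 1.14 and CXCL9 by 4.94 ± 0.81, while CXCL1 changed by -3.77 ± 0.73. The rise of CXCL10 depends on the array, with log2 levels of 10.88, 8.633 and 5.796 in labelled infected 8 h replicates 1, 2 and 3. The chemokine median was -0.34 and the mean 0.24, and the list test passed only without infected 8 h replicate 3 (adjusted p = 0.0408, against 0.308). Of 8 T-cell polarising cytokines 2 were higher, 2 lower and 4 not called (4 when adjusted over the list alone), with IL12B at 6.51 ± 0.75 and TNFSF18 at -4.42 ± 0.62; the median was 0.16 (common median 0.45), and the list test did not pass (adjusted p = 0.156). Of 21 immediate early genes 0 were higher, 10 lower and 11 not called (11 when adjusted over the list alone), with EGR1 at -5.93 ± 0.55. The median was -0.95 (common median -0.66), and the list test gave adjusted p = 0.000751, but adjusted p = 0.302 with an estimated correlation.

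In total 1966 genes were called at labelled 8 h, 486 higher and 1480 lower, and 3137 with the replicate block. The groups did not overlap in 43.1% of genes, where chance gives 10%. The median change of all genes was -0.209, and the share of called genes that were lower was 75.3%, 52.9% after quantile normalization, 39.6% on a common median and 49.9% without the dim filter. The count was 1058 without uninfected replicate 1, 1252 without uninfected replicate 3 and 1018 without infected 8 h replicate 2. 

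Infected 24 h against uninfected 2 h asks what remains of the response at 24 h. Listed, with the sign turned, it is infected 2 h against uninfected 2 h, the pair matched for time under those names. In the arrays labelled infected 24 h, the protease gene KLK4 changed by -3.13 ± 0.28 (adjusted p = 0.000365) and EGR3 by -3.00 ± 0.25 (adjusted p = 0.000348); by the listed names both rose at 2 h, KLK4 by 8.75-fold and EGR3 by 7.99-fold. The growth factor gene HBEGF changed by -2.89 ± 0.33 and NR4A2 by -2.78 ± 0.39 (adjusted p = 0.0109). EGR1 (-2.53 ± 0.55) and DUSP1 (-1.67 ± 0.34) were not called (adjusted p = 0.0961 and 0.0691) but passed with the replicate block (0.0179 for each). Of 21 immediate early genes 0 were higher, 2 lower and 19 not called (10 when adjusted over the list alone) in the arrays labelled infected 24 h. The median was -0.62 (common median -0.75), and the list test gave adjusted p = 1.54e-21, or adjusted p = 0.0118 with an estimated correlation (0.0523 with the replicate block as well). Of 16 inflammatory cytokines limma called 0 (3 when adjusted over the list alone; 4 lower at an unadjusted p under 0.05, 3 lower with the replicate block). The median was -0.25, and the list test gave adjusted p = 2.46e-07, but adjusted p = 0.258 with an estimated correlation. TNF itself did not pass, at -2.97 ± 0.67 (adjusted p = 0.103; 0.00982 with the replicate block). Among 42 interferon-stimulated genes limma called 0, 0 at an unadjusted p under 0.05 and 0 with the replicate block. Their median was 0.07 as labelled and -0.07 as listed, and the list test pointed the other way without passing (adjusted p = 0.428). It passed without uninfected replicate 3 (adjusted p = 0.00434; labelled median -0.12) or infected 24 h replicate 1 (0.0308; labelled median -0.07).

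In total 26 genes were called at labelled 24 h, 16 higher and 10 lower, and 77 with the replicate block and 5 with only the arrays of the 2 groups. The groups did not overlap in 17.5% of genes, where chance gives 10%. The median change of all genes was 0.106, and the share of called genes that were lower was 38.5%, 100% of 7 after quantile normalization and 72.7% of 11 on a common median. The count was 6 without uninfected replicate 2 and 15 without infected 24 h replicate 3, and the call of NR4A2 was lost without uninfected replicate 2 (adjusted p = 0.0693). HBEGF and NR4A2 lost their calls when only the arrays of the 2 groups were fitted (adjusted p = 0.0937 for each). Both kept them in the fit with the replicate block (adjusted p = 0.00565 for each).

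Infected 24 h against infected 2 h asks how the infected cells change over a day. Listed, with the sign turned, it is infected 4 h against uninfected 2 h. The values here are in that listed direction, for the arrays labelled infected 2 h against those labelled infected 24 h. INHBA, a subunit of activin, was higher by 5.74 ± 0.81 on the log2 scale (53.5-fold; adjusted p = 0.000878) and the cytokine gene TNF by 5.00 ± 0.67 (32.1-fold; adjusted p = 0.000691). KLK4 was higher by 3.99 ± 0.28 and IL12B by 3.33 ± 0.75. The log2 levels of IL12B in labelled infected 2 h replicates 1, 2 and 3 were 8.875, 9.805 and 6.681. GIMAP1, GIMAP7 and GIMAP8 changed by -3.86 ± 0.24, -3.65 ± 0.22 and -3.28 ± 0.25 (adjusted p = 2.96e-06 for GIMAP1), and the transcription factor CEBPD by -3.23 ± 0.43. GIMAP1 and GIMAP8 lie under 4 in 1 group, and with it taken at 4 their changes are at least -3.05 and -2.31 in size. Of 16 inflammatory cytokines 7 were higher, 0 lower and 9 not called (10 when adjusted over the list alone). The median was 1.94 (common median 2.33), and the list test gave adjusted p = 2.91e-09, but adjusted p = 0.0982 with an estimated correlation (0.0454 with the replicate block as well). Of 20 chemokines 5 were higher, 0 lower and 15 not called (5 when adjusted over the list alone), with CXCL2 at 3.16 ± 0.72 and CXCL8 at 3.02 ± 0.63. The median was 0.97 (common median 1.36), and the list test gave adjusted p = 1.04e-06, but adjusted p = 0.137 with an estimated correlation. Of 20 NF-kB pathway genes 9 were higher, 0 lower and 11 not called (10 when adjusted over the list alone), with TNFAIP3 at 2.26 ± 0.47 and ICAM1 at 1.74 ± 0.23. The median was 0.74 (common median 1.13), and the list test gave adjusted p = 2.92e-10, but adjusted p = 0.0982 with an estimated correlation. Of 21 immediate early genes 12 were higher, 0 lower and 9 not called (13 when adjusted over the list alone), with DUSP4 at 3.13 ± 0.53 and NR4A3 at 2.79 ± 0.35. The median was 0.87 (common median 1.25), and the list test gave adjusted p = 1.24e-16, or adjusted p = 0.0306 with an estimated correlation. Of 42 interferon-stimulated genes 0 were higher, 2 lower and 40 not called (0 when adjusted over the list alone), with a median of -0.16 as deposited and 0.23 on a common median. Their list test pointed up without passing (adjusted p = 0.172), and passed without infected 24 h replicate 1 (0.0296) or 2 (0.0470). In total 2248 genes were called, 367 higher and 1881 lower in the listed direction, and 3405 with the replicate block. Groups did not overlap in 45.3% of genes, where chance gives 10%, and the median change of all genes was -0.304. In the labelled direction the share of called genes that were lower was 16.3%, 42.5% after quantile normalization, 68.6% on a common median and 72.7% without the dim filter. The count was 1295 without infected 2 h replicate 1, 1165 without infected 2 h replicate 2, 1488 without infected 24 h replicate 1, 1331 without infected 24 h replicate 2 and 1117 without infected 24 h replicate 3.

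Infected 24 h against infected 4 h was added after the data were seen, since its listed names are uninfected 2 h and infected 8 h. The values are in that listed direction, for the arrays labelled infected 4 h against those labelled infected 24 h. CXCL10 was higher by 8.12 ± 1.14 on the log2 scale (9.16 without infected 4 h replicate 3, 7.52 without replicate 1), IL12B by 7.77 ± 0.75 (adjusted p = 3.8e-05; 8.57 without replicate 3) and RSAD2 by 7.26 ± 0.53 (154-fold; adjusted p = 6.23e-06). INHBA was higher by 5.94 ± 0.81, TNF by 4.82 ± 0.67 and IL1B by 3.84 ± 0.93. GPR34 changed by -5.08 ± 0.64, the hydrolase gene NUDT7 by -4.39 ± 0.42, LRRC25 by -4.37 ± 0.33 (adjusted p = 6.73e-06) and SLC40A1 by -3.80 ± 0.68. The log2 levels of SLC40A1 in labelled infected 4 h replicates 1, 2 and 3 were 6.825, 7.87 and 4.72. With groups under 4 taken at 4, the lower bounds in size are 7.46 for CXCL10, -4.83 for GPR34, -3.55 for NUDT7 and -4.17 for LRRC25. Of 42 interferon-stimulated genes 32 were higher, 0 lower and 10 not called (33 when adjusted over the list alone). The median was 2.16 (common median 2.62), and the list test gave adjusted p = 1.01e-27, but adjusted p = 0.120 with an estimated correlation (0.0416 with the replicate block as well). Of 20 maturation and co-stimulation genes 14 were higher, 0 lower and 6 not called (14 when adjusted over the list alone), with CD40 at 3.26 ± 0.45 and CD80 at 2.98 ± 0.49. The median was 1.63 (common median 2.10), and the list test gave adjusted p = 5.48e-11, or adjusted p = 0.0279 with an estimated correlation. Of 16 inflammatory cytokines 9 were higher, 0 lower and 7 not called (10 when adjusted over the list alone). The median was 2.14 (common median 2.61), and the list test gave adjusted p = 1.3e-08, but adjusted p = 0.120 with an estimated correlation (0.0354 with the replicate block as well). Of 20 chemokines 8 were higher, 0 lower and 12 not called (8 when adjusted over the list alone). The median was 1.17 (common median 1.63), and the list test gave adjusted p = 6.92e-06, but adjusted p = 0.122 with an estimated correlation. Of 17 cell cycle genes 0 were higher, 9 lower and 8 not called (9 when adjusted over the list alone), with MCM5 at -2.21 ± 0.26. The median was -1.50 (common median -1.04), and the list test gave adjusted p = 0.0120 (0.117 without infected 4 h replicate 3), but adjusted p = 0.462 with an estimated correlation. In total 4317 genes were called, 901 higher and 3416 lower in the listed direction, and no array left out moved the count by more than 1.5 times. Groups did not overlap in 56.5% of genes, where chance gives 10%. The median change of all genes was -0.372, and the share of called genes that were lower was 79.1%, 58.1% after quantile normalization and 37.9% on a common median. Without the dim filter the excess also turns: 8132 of 12039 called genes were lower in the labelled direction, and 3907 higher.

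Infected 24 h against infected 8 h asks how the late response changes. Listed, with the sign turned, it is infected 24 h against uninfected 2 h. Its values are in that listed direction, for the arrays labelled infected 8 h against those labelled infected 24 h. IDO1 was higher by 6.70 ± 0.87 on the log2 scale (adjusted p = 0.000284; 7.86 without infected 8 h replicate 3, 5.85 without replicate 1), RSAD2 by 6.39 ± 0.53 (adjusted p = 1.78e-05; 7.10 without replicate 3) and EBI3 by 5.14 ± 0.48. SLC40A1 changed by -6.80 ± 0.68 (adjusted p = 5.63e-05), GPR34 by -5.76 ± 0.64 and THBD by -5.41 ± 0.72. These and EBI3 lie under 4 in 1 group, and the lower bounds in size are 4.92 for EBI3, -6.27 for SLC40A1, -4.83 for GPR34 and -4.60 for THBD, and below -3.17 for EGR3. MS4A6A, a membrane protein of myeloid cells, changed by -4.27 ± 0.38 and the scavenger receptor CD163 by -4.14 ± 0.98. Of 42 interferon-stimulated genes 34 were higher, 0 lower and 8 not called (38 when adjusted over the list alone), with CMPK2 at 3.94 ± 0.36. The median was 1.92 (common median 2.34), and the list test gave adjusted p = 1.93e-30, but adjusted p = 0.109 with an estimated correlation (0.0391 with the replicate block as well). Of 20 maturation and co-stimulation genes 12 were higher, 0 lower and 8 not called (13 when adjusted over the list alone), with CCR7 at 3.77 ± 0.50 and LAMP3 at 3.15 ± 0.45. The median was 1.12 (common median 1.54), and the list test gave adjusted p = 5.6e-11, or adjusted p = 0.0403 with an estimated correlation. Of 18 MHC class I presentation genes 10 were higher, 0 lower and 8 not called (13 when adjusted over the list alone), with NLRC5 at 2.31 ± 0.46 and TAP1 at 2.19 ± 0.32. The median was 0.53 (common median 0.95), and the list test gave adjusted p = 6.24e-09, but adjusted p = 0.109 with an estimated correlation (0.0391 with the replicate block as well). Of 24 C-type lectin, Fc, complement and scavenger receptors 1 was higher, 13 lower and 10 not called (14 when adjusted over the list alone), with CLEC5A at -3.26 ± 0.68 and a median of -1.29 (common median -0.87). The list test of those receptors did not pass (adjusted p = 0.0733) but did without infected 8 h replicate 2 (0.0381) or infected 24 h replicate 2 (0.0475), and with the replicate block (0.0201). Of 21 immediate early genes 4 were higher, 9 lower and 8 not called (13 when adjusted over the list alone), with EGR1 at -3.40 ± 0.55 and EGR3 at -3.36 ± 0.25. Their median was -0.28 and their mean -0.69, while the list test against other genes pointed up without passing (adjusted p = 0.968) and down without the dim filter, and the median was 0.14 on a common median. In total 3474 genes were called, 703 higher and 2771 lower in the listed direction. The groups did not overlap in 55.8% of genes, where chance gives 10%, and the median change of all genes was -0.325. In the labelled direction the share of called genes that were lower was 20.2%, 47.3% after quantile normalization, 63.8% on a common median and 71.3% without the dim filter. The count was 2251 without infected 8 h replicate 2 and 2303 without infected 24 h replicate 3.

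Infected 4 h against infected 2 h and infected 8 h against infected 4 h ask what changes from one time to the next. Listed, they are infected 8 h against 4 h and infected 24 h against 8 h. From labelled 2 h to 4 h, RSAD2 was higher by 5.91 ± 0.53 on the log2 scale (adjusted p = 8.45e-05), the death ligand TNFSF10 by 5.89 ± 0.82 and IDO1 by 5.57 ± 0.87. The log2 levels of IDO1 in labelled infected 4 h replicates 1, 2 and 3 were 11.414, 10.345 and 8.431. NR4A2 changed by -4.41 ± 0.39 and EGR3 by -4.22 ± 0.25. Of 42 interferon-stimulated genes 33 were higher, 0 lower and 9 not called (34 when adjusted over the list alone), with ISG20 at 5.21 ± 0.67 (at least 4.89 with the dim group taken at 4). The median was 2.62 (common median 2.70), and the list test gave adjusted p = 4.4e-37, but adjusted p = 0.181 with an estimated correlation. Of 21 immediate early genes 1 was higher, 9 lower and 11 not called (13 when adjusted over the list alone). The median was -0.80 (common median -0.72), and the list test gave adjusted p = 5.27e-06, but adjusted p = 0.181 with an estimated correlation. From labelled 4 h to 8 h, the serotonin receptor gene HTR2B was higher by 3.95 ± 0.40 (adjusted p = 0.000219) and ADTRP by 3.09 ± 0.35. The tight junction gene CLDN1 changed by -5.65 ± 0.90, KITLG by -4.54 ± 0.48 (adjusted p = 0.00027) and GALNT3 by -4.52 ± 0.50 (-3.98 with its dim group taken at 4). Of 16 inflammatory cytokines 0 were higher, 4 lower and 12 not called (6 when adjusted over the list alone). The median was -1.42 (common median -1.46), and the list test gave adjusted p = 0.000168, but adjusted p = 0.265 with an estimated correlation. Of 18 MHC class I presentation genes 5 were higher, 0 lower and 13 not called (11 when adjusted over the list alone). The median was 0.55 (common median 0.51), and the list test gave adjusted p = 0.000128, but adjusted p = 0.265 with an estimated correlation. From 2 h to 4 h 926 genes were called, 451 higher and 475 lower, 1758 with the replicate block and 77 (51 higher, 26 lower) with only the arrays of the 2 groups, with no overlap in 22.9% of genes. From 4 h to 8 h 862 were called, 448 higher and 414 lower, 1705 with the block and 98 (40 higher, 58 lower) with only the 2 groups, with no overlap in 24.0%, where chance gives 10%. The first count was 523 without infected 2 h replicate 1, 545 without infected 2 h replicate 2, 436, 399 and 1937 without infected 4 h replicate 1, 2 and 3. The second was 479, 454 and 1373 without infected 4 h replicate 1, 2 and 3, and 528 without infected 8 h replicate 2.

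Other pathway lists cover metabolism and stress, given here for the arrays labelled infected 4 h against those labelled infected 24 h (listed infected 8 h against uninfected 2 h). Oxidative phosphorylation genes, which serve respiration in mitochondria, depend on the scaling: of 29 measured 0 were higher, 21 lower and 8 not called (23 when adjusted over the list alone), with NDUFS3 at -1.27 ± 0.21 and NDUFA2 at -1.19 ± 0.15. On a common median 2 were higher and 8 lower, and the median went from -0.54 to -0.08. Their list test gave adjusted p = 0.000708, but adjusted p = 0.425 with an estimated correlation. Among 27 glycolysis and hypoxia genes 9 were higher, 5 lower and 13 not called (14 when adjusted over the list alone), with the glucose transporter SLC2A3 at 2.45 ± 0.20. The median was 0.32 (common median 0.78), and the list test gave adjusted p = 0.000209, or adjusted p = 0.0279 with an estimated correlation. The NRF2 and oxidative stress list had 7 genes higher, 2 lower and 7 not called of 16 (11 when adjusted over the list alone), with GCLM at 2.70 ± 0.33. Its median was 0.48 (common median 0.95), with adjusted p = 0.000235, but adjusted p = 0.120 with an estimated correlation. Cell death regulators had 7 higher, 2 lower and 11 not called of 20 (9 when adjusted over the list alone), with CFLAR at 2.01 ± 0.32. Their median was 0.52 (common median 0.99), with adjusted p = 0.000242, but adjusted p = 0.0656 with an estimated correlation (0.0354 with the replicate block as well).

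In that same comparison, heat shock and unfolded protein genes had 5 higher, 1 lower and 11 not called of 17 (5 when adjusted over the list alone), with ATF3 at 1.64 ± 0.41. Their median was 0.04 (common median 0.50), with adjusted p = 0.00368, but adjusted p = 0.122 with an estimated correlation (0.0416 with the replicate block as well). Cholesterol synthesis and uptake genes had 4 higher, 1 lower and 12 not called of 17 (3 when adjusted over the list alone), with INSIG1 at 1.23 ± 0.14 and PMVK at -2.56 ± 0.20. Their median was 0.05 (common median 0.51). Their list test gave adjusted p = 0.0148, lost without infected 4 h replicate 3 (0.0598) or infected 24 h replicate 2 (0.0956), and adjusted p = 0.462 with an estimated correlation; its direction reversed without the dim filter. The list of liver X receptor targets and lipid efflux genes had 0 higher, 4 lower and 8 not called of 12 (4 when adjusted over the list alone), with ABCG1 at -3.36 ± 0.54. Its median was -1.14 (common median -0.68), and the list test did not pass (adjusted p = 0.354). Phagosome, oxidase and lysosome genes had 3 higher, 7 lower and 12 not called of 22 (10 when adjusted over the list alone), with NCF4 at -2.34 ± 0.24; on a common median 5 were higher and 2 lower. Their median was -0.50 as deposited and -0.03 on a common median, while the list test pointed up without passing (adjusted p = 0.905). Tryptophan, arginine and prostaglandin enzymes had 5 higher, 4 lower and 4 not called of 13 (10 when adjusted over the list alone), with IDO1 at 5.41 ± 0.87. Their median was 0.32 (common median 0.78), and the list test passed only without infected 24 h replicate 1 (adjusted p = 0.0408, against 0.0663).

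At the next time, for the arrays labelled infected 8 h against those labelled infected 24 h (listed infected 24 h against uninfected 2 h), 6 of 7 metallothioneins were higher, 0 lower and 1 not called (6 when adjusted over the list alone), with MT1G at 2.95 ± 0.61. Their median was 2.54 (common median 2.96), and the list test gave adjusted p = 4.72e-05, but adjusted p = 0.332 with an estimated correlation. Ribosomal protein genes depend on the scaling: of 17 measured 0 were higher, 13 lower and 4 not called (13 when adjusted over the list alone), with a median of -0.57, while on a common median 1 was lower and the median was -0.15. Their list test gave adjusted p = 0.0041, but adjusted p = 0.542 with an estimated correlation.

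**Figure D3:**
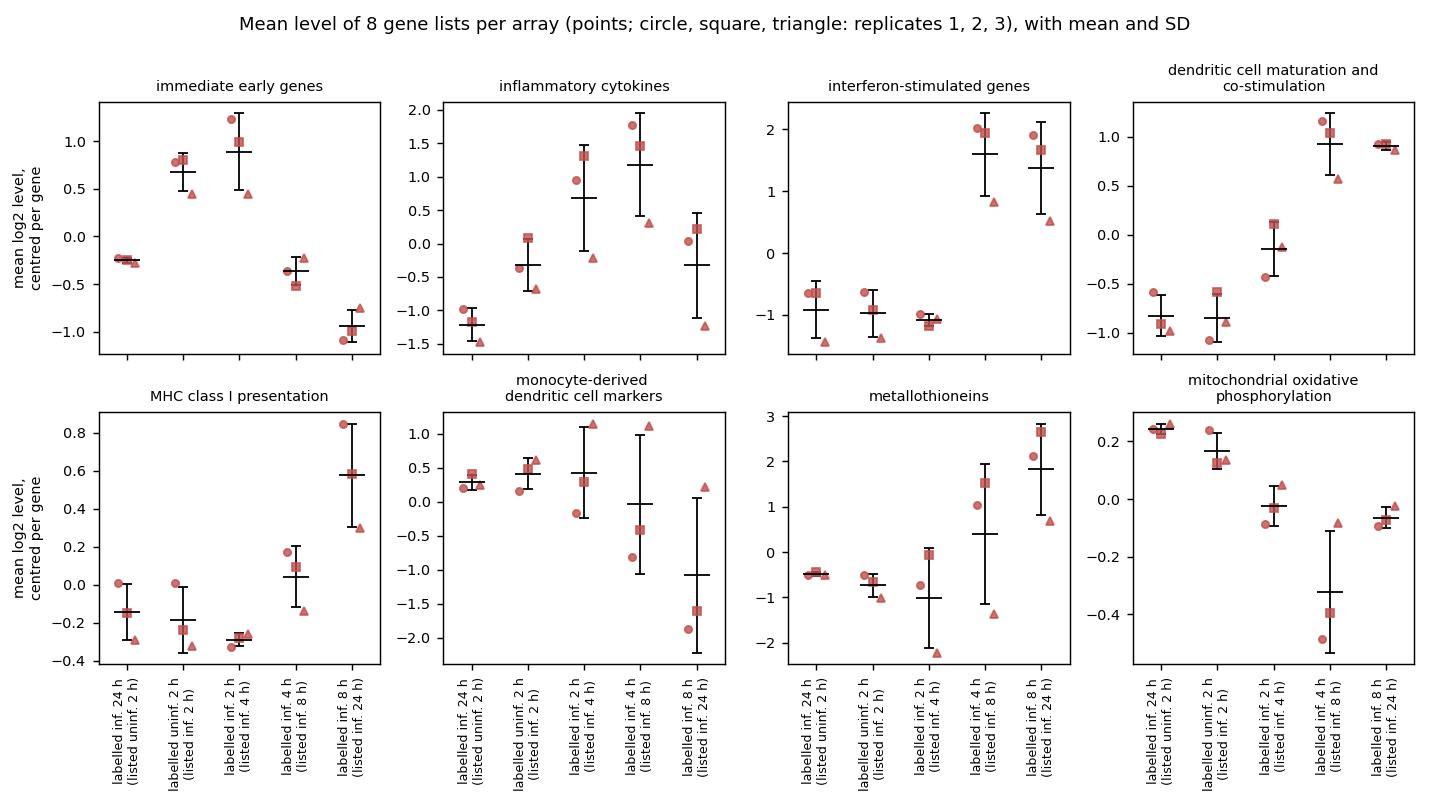
Mean level of 8 gene lists on each of the 15 arrays (log2, centred on each gene's mean over the arrays), by group under both names, with the mean of 3 arrays as a bar. The interferon-stimulated genes lie between 0.524 and 2.02 on the 6 arrays labelled infected 4 h and 8 h and between -1.45 and -0.631 on the other 9.

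**Figure D4:**
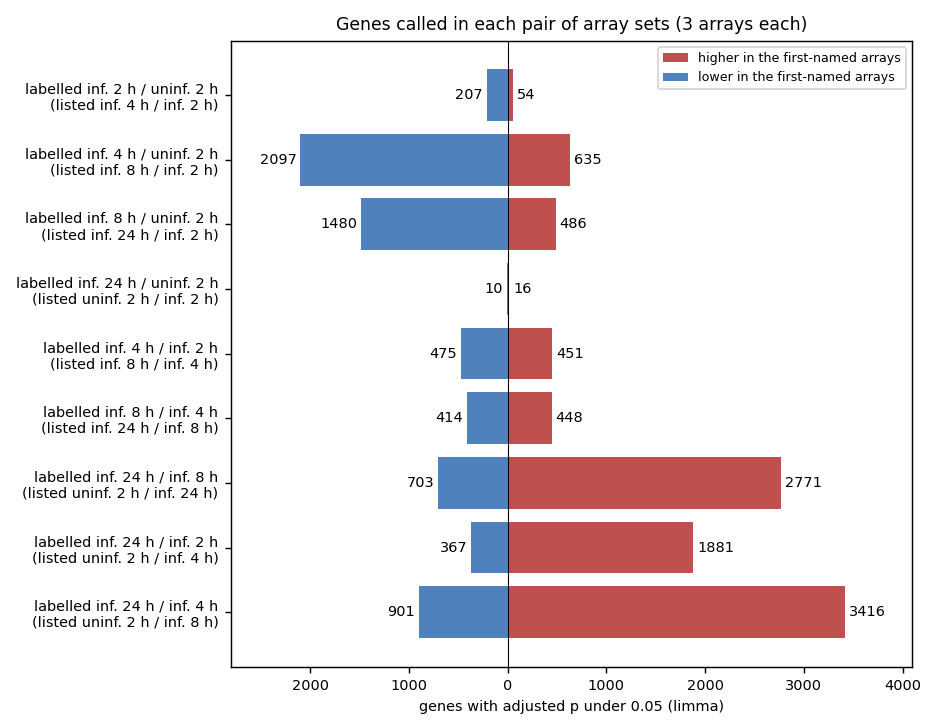
Number of genes called higher and lower in each comparison, with both names of each pair of groups. The counts run from 26 for the arrays labelled infected 24 h against uninfected 2 h to 4317 for those labelled infected 24 h against infected 4 h.

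The authors' deposited table gives its own fold changes, against the arrays it lists as uninfected. In the authors' deposited table EGR3 has a fold of 9.31 at 2 h; CSF1 has 7.55 and GIMAP7 0.0899 at 4 h. At 8 h the authors' deposited table gives CD40 a fold of 16.4 by 1 probe set and 10.1 by another, and LRRC25 0.0716. At 24 h it gives SLC1A2 18.9 and SLC40A1 0.0135. Across its 848 probe sets, the log2 folds of the authors' deposited table correlate with those computed here by the listed names at 0.991, 0.986, 0.989 and 0.988 for 2, 4, 8 and 24 h, and by the labels at 0.384, 0.464, 0.622 and -0.159. The listed names were set by matching these same columns. High correlations by those names were therefore bound to follow and are no evidence for them. Of the 848, 807 were called by the F test over probe sets, which called 8050 of 19566, so that 349 would be called if the lists were independent. The authors' deposited table was chosen on these same arrays, so this overlap is not independent evidence. In all, 1919 probe sets of the value table reach the highest p of the authors' deposited table by the same test, and 676 of those are in it.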

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

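The tests on displaced conditions and on dendritic cell markers were chosen only after the result was seen, as were every reading by the listed names and the changes with a dim group taken at the filter bound.

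For 5 results, some by the labels and the others by the listed names, the change from uninfected goes in opposite directions at 2 h and 24 h. The 2 readings exclude each other, so the 5 do not hold together. The 4 genes were picked because both changes were called, so a test of their difference was bound to pass and its p is not given. By the labels, GIMAP8 changed by -1.59 ± 0.25 at 2 h and 1.69 ± 0.25 at 24 h, a difference of 3.28 ± 0.25, and PLPP6 by -1.23 ± 0.16 and 0.94 ± 0.16, a difference of 2.17 ± 0.16. Both are dim in the arrays labelled infected 2 h, with mean log2 levels of 3.03 and 2.91, under the filter bound of 4; with that group taken at 4 the changes at 2 h are -0.62 and -0.14 and the differences 2.31 and 1.08. At 24 h GIMAP8 was not called after quantile normalization (1.45), with only the arrays of the 2 groups (1.69) or without uninfected replicate 2 (1.69). PLPP6 was not called there after quantile normalization (0.71), on a common median (0.82), with only the 2 groups (0.94), without uninfected replicate 1, 2 or 3 (0.99, 0.88, 0.97) or without infected 24 h replicate 2 or 3 (0.83, 0.89). The immediate early genes had a labelled median of 0.39 at 2 h and -0.62 at 24 h. The median of their differences was -0.87, and the list test of the difference gave adjusted p = 0.0306 at an estimated correlation. This list was taken because that test passed, with no condition on its changes at 2 h and 24 h. Between these 2 groups the listed names are infected 4 h and uninfected 2 h.

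By the listed names EGR3 had a mean log2 level of 7.17 in uninfected cells, 10.17 at 2 h and 3.81 at 24 h, and the difference between the changes was -6.36 ± 0.25. The level at 24 h lies under the filter bound of 4, and taken at 4 the difference is -6.17. NR4A2 changed by 2.78 ± 0.39 and -1.79 ± 0.39, a difference of -4.57 ± 0.39. Its 2 h call was lost with only the arrays of the 2 groups (2.78) and without labelled uninfected replicate 2 (2.56). That call held in the fit with the replicate block (adjusted p = 0.00565). Under the labels these 2 differences are infected 8 h against uninfected 2 h.

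A signal also appears in data outside the gene counts. Of 1691 kept probe sets that name no gene, 563 differed among the 5 groups by the F test, or 33.3%, against 41.9% of those that name 1 or more.

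The value table and the authors' deposited table place the same 15 arrays in different conditions. If the columns of the value table were displaced, the 6 lists of inducible genes would be lowest in the arrays listed uninfected, and 3 of 6 are: NF-kB pathway genes, inflammatory cytokines and chemokines. If the headings of the authors' deposited table were displaced, the lists would be lowest in the arrays labelled uninfected, and 1 of 6 is, the maturation list, by -0.854 against -0.826 in the arrays labelled infected 24 h. The interferon-stimulated genes are lowest in the arrays labelled infected 2 h (-1.08, against -0.98 labelled uninfected) and the immediate early genes in those labelled infected 8 h. Neither count reaches 5 of 6, the bound set for each explanation. The interferon-stimulated genes lie at -0.91 in the arrays listed uninfected, near both values above. The maturation values also lie close, so the place of these lists decides little. Inflammatory cytokines lie at -1.21 in the arrays listed uninfected and -0.32 in those labelled uninfected, chemokines at -0.92 and -0.27, NF-kB pathway genes at -0.55 and -0.42. Immediate early genes lie at -0.252 in the arrays listed uninfected and 0.677 in those labelled uninfected. The bound of 5 of 6 was set after the result was seen, and the count includes lists with near-equal levels. It therefore cannot decide between displaced columns and displaced headings. The lists with wider gaps all lie lower in the arrays listed uninfected, the side that displaced columns would give. Those gaps were not tested, and no biological explanation was tested.

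More genes were lower than higher in the arrays labelled infected 4 h (listed infected 8 h) than in those labelled infected 24 h (listed uninfected 2 h), 79.1% of called genes. Dim probe sets near background are argued against as the whole cause, since 72.3% of the 1691 called genes with a mean log2 level above 8 were lower, 1222 genes. Scaling of the arrays stays open: 37.9% were lower after each array was shifted to a common median and 58.1% after quantile normalization, so a shift of whole arrays and a change in most genes cannot be told apart. Without the dim filter the excess turns as well, with 8132 of 12039 called genes lower in the labelled direction, and the cause was not tested. A biological fall in most transcripts with infection or time stays open and was not tested.

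Dendritic cell markers were lower in the arrays labelled infected 8 h (listed infected 24 h) than in those labelled infected 24 h (listed uninfected 2 h), 9 of 16 measured. A lower share of dendritic cells would raise the markers of other cell types. Of these 3.7% were higher, 1 of 27 (MMP9, 1.21 ± 0.23), and 7 were lower. This count cannot decide, since most of the 27 are macrophage or monocyte markers and the cells were grown from monocytes. It was also taken on the deposited scale, where 79.8% of called genes were lower. Of the dendritic markers 1 is also in the macrophage list. Scaling stays open: 4 of 16 were still lower on a common median, between the bounds set for it (2) and against it (5), so it cannot be told apart from a fall in the markers. After quantile normalization, which had no bound, 6 were. These are counts of calls: the median change of the markers, given with the cell type lists below, was smaller on a common median but still a fall. A change of these markers with infection or time stays open and was not tested.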

How the results depend on the processing

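The reading by the listed names and the added comparison, infected 24 h against infected 4 h, were chosen only after the result was seen; the other alternatives were planned. Values below are counts of called genes, or the median log2 change of the interferon-stimulated genes where that list is named. Where no cause is given, the cause was not tested.

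Of the named genes' results, 944 kept their direction and their side of the threshold with the replicate block, 1079 without the intensity trend, 1038 without the dim filter, 968 with a stricter one, 995 after quantile normalization, 937 on a common median, 1030 with the mean of all probe sets and 946 with only the arrays of the 2 groups. Calls were gained with the replicate block in 138 and lost in 0. They were lost after quantile normalization in 49, on a common median in 80 and with only the 2 groups in 111. TMEM37 at labelled 24 h reversed to 0.35 with the stricter filter and 0.20 with the mean of all probe sets (listed 2 h: -0.35 and -0.20). List results kept their side in 176 cases with an estimated correlation and lost it in 80.

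The replicate block, which uses the pairing by donor, gave 765 genes for infected 2 h against uninfected (261 as reported), 3137 for 8 h (1966), 77 for 24 h (26), 1758 for 4 h against 2 h (926), 1705 for 8 h against 4 h (862) and 3405 for 24 h against 2 h (2248). Only the arrays of the 2 groups, a fit with fewer arrays, gave 43 for 2 h, 1246 for 4 h (2732), 5 for 24 h, 77 for 4 h against 2 h and 98 for 8 h against 4 h.

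Quantile normalization gave 154 for 2 h, 7 for 24 h and 1247 for 24 h against 2 h; a common median gave 11 for 24 h, and 0.16 for the interferon-stimulated genes at 2 h, against -0.11, where the list test turned down without passing. The stricter dim filter gave 7 for 24 h. A pseudocount of 16 gave 116 for 2 h, and medians of -0.09 at 2 h and 0.05 at 24 h (listed: -0.05 at 2 h, -0.15 at 4 h), where the list test turned direction without passing.

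The stricter thresholds call fewer genes by construction. A minimum of 2-fold gave 167, 1349, 985 and 16 for 2, 4, 8 and 24 h against uninfected, 498 for 4 h against 2 h, 464 for 8 h against 4 h, 1607 for 24 h against 8 h, 932 for 24 h against 2 h and 2144 for 24 h against 4 h. Adjusted p under 0.01 gave 62, 1261, 755 and 5, then 349, 274, 1672, 782 and 2498 in that order, and 2447 by the F test (4568).

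Signal over background limits what dim probe sets show. Without the dim filter the counts were 130 for 2 h, 57 for 24 h, 610 for 4 h against 2 h, 11713 for 24 h against 8 h (3474), 9792 for 24 h against 2 h, 12039 for 24 h against 4 h (4317) and 11735 by the F test. The direction of most calls turned with it: 71.3% were lower for 24 h against 8 h (20.2% with the filter), 72.7% for 24 h against 2 h (16.3%) and 67.5% for 24 h against 4 h (20.9%), and for 8 h against uninfected 49.9% (75.3%). The probe sets under the filter have a median log2 level of 2.71 in the arrays labelled infected 24 h and 2.74 to 2.79 in the other groups; whether that gap makes these calls was not tested. Medians of the interferon-stimulated genes were then -0.09 at 2 h and 0.07 at 24 h (listed: -0.07 at 2 h, -0.16 at 4 h), with a list test that pointed the other way than in the report and did not pass. Without this filter 46 list calls were lost and 35 gained, and the direction of 18 list tests reversed; the cause was not tested. These are phagosome genes at 2 h (-0.20), and at labelled 24 h MHC class II (-0.05), heat shock (-0.07) and tryptophan enzymes (-0.02), with the listed 2 h values 0.05, 0.07 and 0.02. At listed 4 h they are glycolysis (0.05), cholesterol (0.20), tryptophan enzymes (0.02) and cell death (0.04), at listed 8 h MHC class I (0.06), phagosome (-0.50) and cholesterol (0.05), and at listed 24 h glycolysis (0.08), cholesterol (-0.26), immediate early (-0.20) and cell death genes (0.15).

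With fry, which tests a list against no change and not against other genes, the interferon-stimulated genes had the other direction, without passing, at 2 h (-0.11) and 24 h (0.07; listed: -0.07 at 2 h, -0.16 at 4 h), and the immediate early genes reversed at listed 24 h (-0.28). With an estimated correlation the interferon-stimulated genes lost their call at 4 h (2.39) and 8 h (2.14; listed 8 h 2.16 and 24 h 1.92).

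Groups by the listed names gave 26 for 2 h, 4317 for 8 h, 3474 for 24 h, 261 for 4 h against 2 h, 862 for 24 h against 8 h and 1554 for 24 h against 4 h. The interferon-stimulated genes then had -0.16 at 4 h, no longer past the threshold, and 1.92 at 24 h, where the test reversed; other arrays carry the names. With probe sets in place of genes the F test called 8050 of 19566.

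Leaving out each array in turn gave 62 to 418 for 2 h, 1600 to 3641 for 4 h, 1018 to 2001 for 8 h, 6 to 38 for 24 h, 399 to 1937 for 4 h against 2 h, 454 to 1373 for 8 h against 4 h, 2251 to 3323 for 24 h against 8 h, 1117 to 2260 for 24 h against 2 h, 3007 to 4862 for 24 h against 4 h and 3593 to 5181 by the F test. The interferon-stimulated genes ranged from -0.37 to 0.02 at 2 h, 2.08 to 2.70 at 4 h, 1.83 to 2.51 at 8 h and -0.12 to 0.29 at 24 h. By the listed names they ranged from -0.29 to 0.12, -0.40 to 0, 1.95 to 2.67 and 1.69 to 2.28. The report names the arrays that move a count by more than 1.5 times. Named genes kept their side in 5715 such results and lost their call in 583.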

Other observations

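The splits of the arrays were planned, except that of the added comparison and the regrouping within donors; these, the levels by replicate and the cell type counts below were chosen only after the result was seen.

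With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In each comparison 1 of 10 splits, the real one, called as many genes. For infected 2, 4, 8 and 24 h against uninfected 2 h the real split called 261, 2732, 1966 and 26 genes, and the highest of the others 1, 1, 0 and 8. For infected 4 h against 2 h, 8 h against 4 h, 24 h against 8 h and 24 h against 2 h it called 926, 862, 3474 and 2248, and the highest other 0, 8, 0 and 2. For the added 24 h against 4 h it called 4317, and the highest other 0. The real split parts all 3 donor pairs; of the others that do so, the highest called 1 gene, for infected 4 h against uninfected, and the counts of 8, of 2 and of 1 for infected 2 h come from splits that part 1 pair. By the F test 1 of 100 regroupings of the 15 arrays, the real one, called as many genes, 4568 against 524 in the highest other. Those regroupings ignore the donors; of 100 regroupings within donors 1, the real one, called as many, and the highest other called 421, so chance can be excluded there.

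Replicate 3 had lower list levels in some groups. The mean centred log2 level of the interferon-stimulated genes in replicates 1, 2 and 3 was 2.02, 1.94 and 0.828 in the arrays labelled infected 4 h, and 1.92, 1.67 and 0.524 in those labelled infected 8 h. For inflammatory cytokines it was 0.958, 1.31 and -0.22 at labelled 2 h, 1.77, 1.46 and 0.306 at labelled 4 h, and 0.043, 0.213 and -1.23 at labelled 8 h.

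Cell type lists are given for the arrays labelled infected 8 h against those labelled infected 24 h (listed infected 24 h against uninfected 2 h). Of 16 monocyte-derived dendritic cell markers 0 were higher, 9 lower and 7 not called (11 when adjusted over the list alone), with CD1C at -1.56 ± 0.38 and a median of -1.43 (common median -1.01); the list test passed only without infected 8 h replicate 3 (adjusted p = 0.0264, against 0.262). Of 12 macrophage markers 0 were higher, 7 lower and 5 not called (7 when adjusted over the list alone), with CD163 at -4.14 ± 0.98, a median of -1.01 and adjusted p = 0.162. Of 5 monocyte markers limma called 0, with 2 lower at an unadjusted p under 0.05 and 1 higher and 2 lower with the replicate block; the median was -1.50, and adjusted p = 0.791. Of 6 plasmacytoid dendritic cell markers 1 was higher, 1 lower and 4 not called (2 when adjusted over the list alone), with a median of -0.03, a mean of 0.08, a list test that pointed up and adjusted p = 0.262.

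In the same arrays, limma called 0 of 2 T cell markers (1 when adjusted over the list alone), with 1 higher at an unadjusted p under 0.05 and 1 higher with the replicate block, a median of 0.66 and adjusted p = 0.262. Of 2 B cell markers 1 was lower and 1 not called (1 when adjusted over the list alone), with a median of -1.11 and adjusted p = 0.497. Of 3 platelet markers limma called 0, with 1 higher at an unadjusted p under 0.05 and 1 higher and 1 lower with the replicate block; the median was 0.57, and adjusted p = 0.262. Of 3 neutrophil markers 1 was higher, 0 lower and 2 not called (1 when adjusted over the list alone), with MMP9 at 1.21 ± 0.23; the median was -0.48 while the list test pointed up (adjusted p = 0.269). Of NK cell markers 1 was measured and not called, and of erythroid markers 0 were measured, so those 2 lists were not tested.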
